A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

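RNA-seq libraries of rice egg cells, sperm cells and pollen vegetative cells were analysed, 3 of each, in the groups the labels give. Per the labels' protocols, egg cells were dissected from ovaries and extracted with the RNAqueous-Micro kit, and sperm cells were released from pollen in sucrose, separated on Percoll and extracted with the RNeasy Plant Mini kit. The vegetative material came from each sperm isolation, which the labels call paired, while the submitters treated the libraries as independent when the egg was included. The submitters' processing notes name CASAVA 1.8.0, TopHat2 2.0.5 and edgeR, without roles. The genome build, annotation release, read counter and strand setting are not given in the sources used here.

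The deposited tables hold raw read counts and TPM for 1 isoform per locus. Per the file headers, the deposited counts are whole numbers per library with no scaling, and the columns of the deposited TPM table each sum to the same total. The ratio of counts to TPM gave a whole number of bases for 100% of loci within 0.001, so the TPM used isoform lengths. Some of these isoforms were short or long for the gene named (MET1a, MET1b, CMT3a, CMT2, AGO16, NRPD1a, NRPD1b and CMT3b), so counts for them can cover part of a gene. Genes with near-identical copies (light-harvesting proteins, Rubisco small subunits, histone H3 and beta-expansins) are uncertain because the counting could split their reads, and so are overlapping or antisense genes.

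Identifiers are those of the files. A RefSeq gene table (assembly ASM3414082v1) matched 1 of 36029 identifiers, so it could not supply names. The names in the text were written with their identifiers, as 18 lists of 171 entries, before the data were examined, and were recalled from published nomenclature and not from a table. They carry that uncertainty. Of the entries, 164 were in the count table. For 58 entries whose name is held by that entry alone, the RefSeq table had the same symbol or synonym, and for 54 the chromosome was the same, for 2 more several chromosomes included it, and for 2 (UBQ5 and GAPC) it differed. No single-gene value is given for those 2, but both loci stay in the reference list, so its counts and tests, and the list members counted in the egg set, include them. The place along the chromosome had a median gap of 0.842% of its length, and 56 lay within 10%, where chance gives 19.7%. Names shared by several entries, such as H3, were excluded from that check after a first version that included them. The RefSeq table had no match for any sperm cell marker, for the egg marker ECA1-1, or for the YUC and BBM genes. Of the pollen vegetative cell markers the check reached only SUT1. Names without a match, DCL1, NRPE1, CMT3b and ROS1a among them, stayed unchecked. A further 8 lists that needed gene descriptions were not run.

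Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci were kept by edgeR's expression filter (minimum count 10, minimum total 15), which left 19942 of 36029. Libraries were scaled by TMM, with factors from 0.341 to 2.58, and all 9 libraries entered 1 quasi-likelihood fit without a block. Each comparison was tested two-sided with Benjamini-Hochberg adjustment over all tested loci at a threshold of 0.05. The common biological coefficient of variation was 0.350. Normalised CPM are edgeR's CPM over the TMM-scaled library size, and unscaled CPM are CPM over the library total. Folds against a group with no counts use a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% binomial interval. These cover counting error only and use the TMM-scaled library sizes, so another scaling would move them. TMM factors were largest in egg, so folds of sperm or vegetative cell over egg would be lower without composition scaling. Detection required at least 1 unscaled CPM in every library of a group.

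Lists of at least 5 measured genes were tested with camera (limma 3.58.1, correlation preset at 0.01), adjusted over 42 list tests. None of the 13 list calls held with an estimated correlation. Counts of list members are over all loci. Adjusted over the list alone they were the same except for 7 higher and 2 lower replication genes and 0 higher and 4 lower demethylation genes (sperm against egg and vegetative cell against egg), and in sperm against vegetative cell for 0 higher and 1 lower egg marker, 0 photosynthesis genes called, and 3 higher and 1 lower histone H3 genes. Named genes followed a rule fixed before the data were examined: per list and comparison up to 4 members with the smallest adjusted p, marker lists of up to 8 in full, the reference genes, and per direction the 2 most abundant loci with a log2 fold change of at least 2 and non-overlapping libraries. The rule allowed 228 results, all of which entered the sensitivity tables. Examples in the text were chosen among them, and sperm levels per library added, after values were seen. Members named among cell-type sets, and per-library values, are outside the rule and were also chosen then.

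Simulated counts on the real loci, with 200 changed genes, tested the pipeline. At a 4-fold change 60.5% were recovered for sperm against egg, 45.5% for vegetative cell against egg and 51% for sperm against vegetative cell. At 8-fold the shares were 84.5, 86.5 and 85.5%, and at 2-fold 0% in each. With only 200 of 19942 genes changed, the adjusted threshold is stricter than in the real fits, so these shares are not the recovery of those fits. Pairing was checked by correlating the deviations of same-numbered libraries from their group means. Sperm and vegetative libraries of the same number gave 0.017, -0.007 and 0.031, so pairing rests on the labels, with shared numbers presumed to mark the shared isolation.

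Alternatives were other scalings (RLE, upper quartile, none), no filter or a CPM filter, DESeq2 1.42.0, edgeR's exact test, limma on log2 TPM with pseudocounts of 1 and 0.1, a minimum fold of 2, only the 2 groups compared, a replicate block, each library left out, and fry. Leaving out the 3 most abundant loci, and cell-type sets and list tests without composition scaling, were added after the data were seen. An alternative on isoform rows could not be run since the files hold 1 isoform per locus. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.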

Results

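RNA-seq was used to profile transcripts of 3 cell types of rice (Oryza sativa Japonica Group), with 3 libraries each. The egg cell is the female gamete. Sperm cells are the male gametes carried inside the pollen grain, and the vegetative cell is the pollen cell that encloses them and forms the pollen tube. Each egg library came from 50 egg cells dissected from ovaries of greenhouse plants of the cultivar Kitaake. The sperm libraries came from field-grown plants of a recombinant inbred line of Nipponbare and HEG4. The vegetative libraries held the sperm-depleted pollen material left by those isolations. The count table held 36029 loci. Total counts ran from 4067427 to 4611613 in the egg libraries, from 4663178 to 5938560 in the sperm libraries and from 7678464 to 9862809 in the vegetative libraries. The 100 most abundant loci took 16.9 to 27.1% of the counts in egg libraries, 31.2 to 46.0% in sperm libraries and 45.3 to 48.5% in vegetative libraries. No egg library shared its cultivar, growth site or extraction kit with a sperm or vegetative library, so those factors could not be separated from cell type in any comparison with the egg.

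Levels are given as normalised CPM, counts scaled to the effective library size as mean ± SD over n = 3 libraries. Fold changes are on the log2 scale with adjusted p from edgeR's quasi-likelihood test. That test gives no standard error. The SE printed here is an approximation, the absolute log2 fold change divided by the square root of the test's F statistic. At least 1 unscaled CPM in every library of a cell type was found for 17996 loci in the egg, 13185 in sperm and 10405 in the vegetative cell. TMM factors were 2.20 to 2.58 in egg and 0.341 to 0.408 in the vegetative cell. The same cutoff therefore stood at a higher normalised CPM in the vegetative cell, and the order of these numbers partly reflects library composition. Of the detected loci, 7651 were detected in all 3 cell types, while 6281 were detected in the egg alone, 1700 in sperm alone and 612 in the vegetative cell alone. At a minimum of 5 CPM the sperm and vegetative numbers were 8296 and 5949. The egg libraries also held ovule, carpel and photosynthesis transcripts, given below. For loci detected in egg, expression in the egg cell was not separated from ovary tissue.

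**Figure D1:**
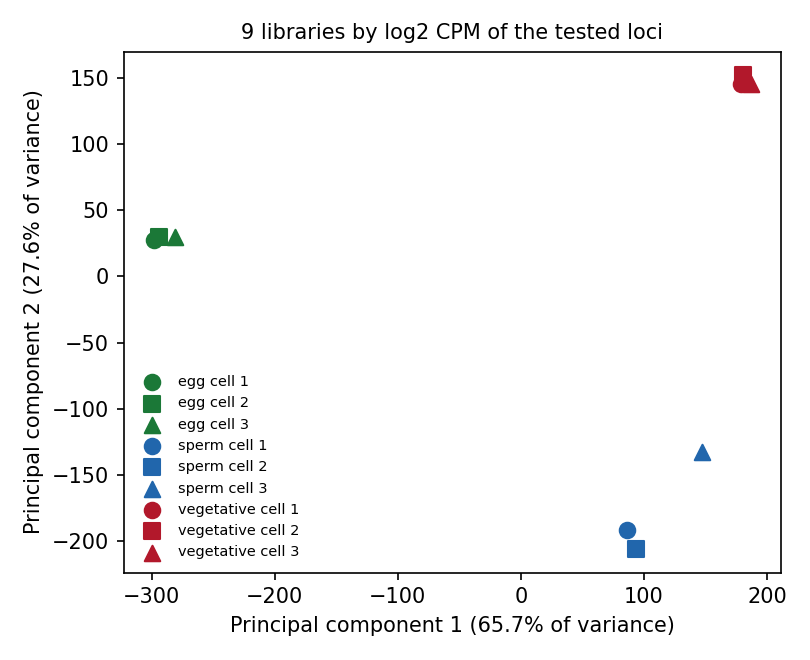
Principal components 1 (65.7% of variance, x axis) and 2 (27.6%, y axis) of log2 CPM over the 19942 tested loci, with colours for cell types and shapes for replicates. The 9 libraries fell into 3 groups by cell type, with sperm replicate 3 nearer to the vegetative libraries than sperm replicates 1 and 2.

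Markers of the cell types were compared first. Of 7 sperm cell markers listed, DMP3 and DMP6 did not pass the expression filter. All 5 measured sperm cell markers were higher in sperm than in egg, and they were also higher in sperm than in the vegetative cell. GEX2 (LOC_Os09g25650), a sperm membrane protein, averaged 2573 ± 673 in sperm, 221 ± 10.3 in the vegetative cell and 3.86 ± 0.851 in egg (log2 fold change 9.37, SE 0.61, adjusted p = 3.0e-08 for sperm against egg). HAP2/GCS1 (LOC_Os05g18730), the gamete fusion factor, averaged 1132 ± 198 in sperm, 147 ± 13.1 in the vegetative cell and 2.55 ± 0.226 in egg. The egg marker ECA1-1 (LOC_Os03g18530), a small cysteine-rich protein, averaged 109 ± 38.4 in egg and 0.621 ± 0.53 in the vegetative cell (log2 fold change -7.41, SE 0.52, adjusted p = 7.6e-08). It had 2 counts over the 3 sperm libraries, a ratio of egg to sperm of 921 (95% interval 255 to 7605).

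Of 10 measured pollen vegetative cell markers, 9 were lower in sperm than in the vegetative cell and 1 did not pass the test, and without composition scaling 8 were lower. The beta-expansin LOC_Os03g01640 (EXPB), a wall-loosening protein of grass pollen, averaged 3678 ± 491 in the vegetative cell and 282 ± 254 in sperm (log2 fold change -3.71, SE 0.66, adjusted p = 0.00026). RUPO (LOC_Os06g03610), a pollen tube receptor-like kinase, averaged 10274 ± 1789.7 in the vegetative cell and 507 ± 481 in sperm. The 3 sperm libraries were unequal for these genes. The beta-expansin measured 143, 127 and 575 in sperm replicates 1, 2 and 3, and RUPO measured 196, 263 and 1060.5. Across 1644 sperm-enriched loci of at least 50 CPM, the unscaled CPM in the vegetative libraries had a median of 6.44% of that in sperm replicates 1 and 2, with quartiles of 3.75 and 10.3%. As normalised CPM the median was 20.9% (12.1 and 33.0), and the loci had been chosen for being lower in the vegetative cell.

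Markers of other flower tissues were seen in the egg libraries. All 8 ovule and carpel markers and all 17 photosynthesis genes measured were higher in egg than in sperm, and all were also higher in egg than in the vegetative cell. The MADS1 (LOC_Os03g11614) call between sperm and egg (log2 fold change -1.85, SE 0.64, adjusted p = 0.016) was lost without egg replicate 1, at -1.64, or without sperm replicate 2, at -1.55. MADS13 (LOC_Os12g10540), an ovule identity gene, averaged 149 ± 11.95 in egg, 0.289 ± 0.393 in sperm and 1.37 ± 0.552 in the vegetative cell. A light-harvesting protein gene, LOC_Os09g17740 (LHCB), averaged 83.9 ± 26.6 in egg and 1.51 ± 0.779 in sperm. The summed unscaled CPM of the photosynthesis genes was 1011, 1659 and 1235 in egg replicates 1, 2 and 3, against at most 6.43 in a sperm library and 3.35 in a vegetative library. The summed unscaled CPM of the ovule and carpel markers was 935, 909 and 782 in the egg libraries, against at most 3.73 in a sperm library and 2.03 in a vegetative library.

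**Figure D2:**
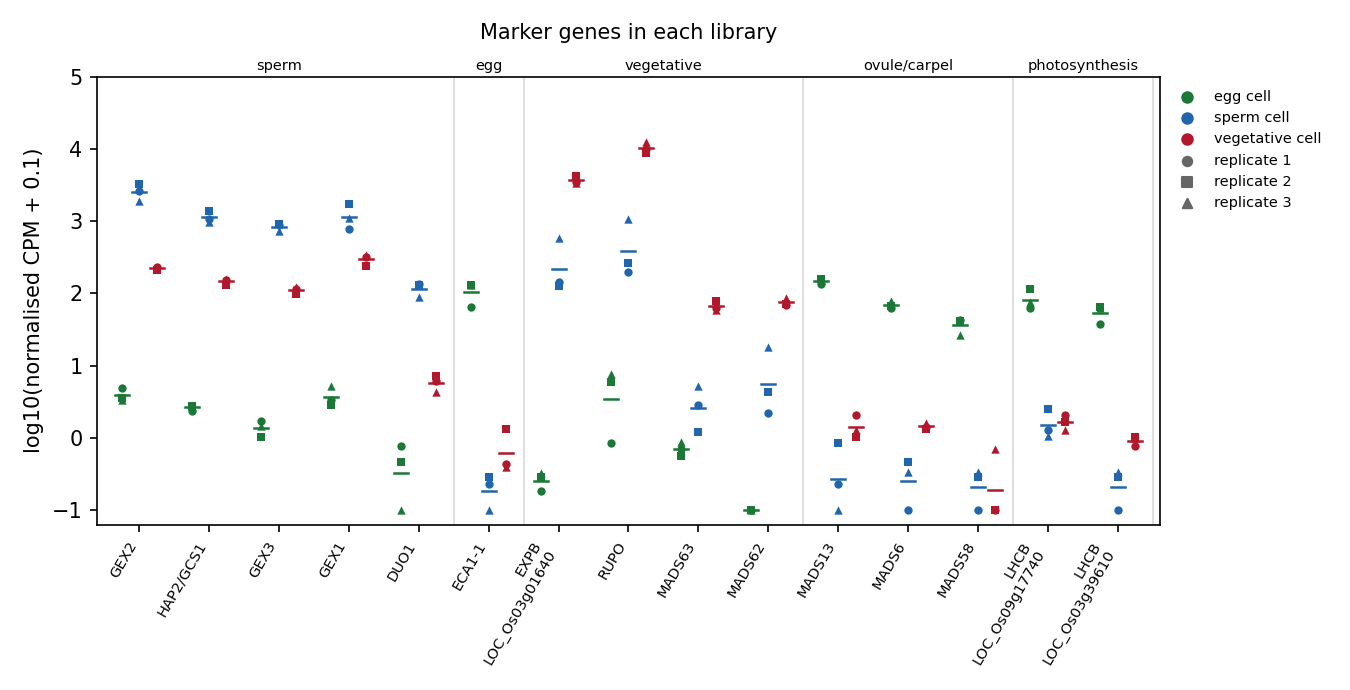
Marker genes (x axis) in each library as log10 of normalised CPM plus 0.1 (y axis), with colours for cell types, shapes for replicates and bars for the mean of the plotted values. Sperm markers were highest in the sperm libraries (GEX2 at 2573 on average), and ovule, carpel and photosynthesis genes were highest in the egg libraries (MADS13 at 149).

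Sperm against egg asked how the male and female gametes differ before fertilisation. The egg libraries also held the ovule, carpel and photosynthesis transcripts above. For genes called higher in egg, here and against the vegetative cell, expression in the egg cell was not separated from ovary tissue. The ARGONAUTE family, the proteins that bind small RNAs, was split: of 16 measured members 8 were higher in sperm and 8 were higher in egg. AGO2 (LOC_Os04g52540) averaged 509.8 ± 99.6 in sperm and 32.7 ± 3.16 in egg (log2 fold change 3.96, SE 0.34, adjusted p = 2.6e-07), and AGO13 (LOC_Os03g57560) averaged 75.5 ± 10.2 and 7.14 ± 1.24 (3.40, SE 0.29, adjusted p = 2.4e-07). AGO4b (LOC_Os04g06770), of the clade that acts in RNA-directed DNA methylation, averaged 113 ± 18.7 in egg and 2.43 ± 1.73 in sperm (log2 fold change -5.47, SE 0.51, adjusted p = 5.3e-07). PNH1 (LOC_Os06g39640), an AGO1-clade member, averaged 50.6 ± 16.9 in egg and had 1 count in sperm, an egg to sperm ratio of 848 (95% interval 152 to 33513). The list test found no common direction (adjusted p = 0.79), and without composition scaling 5 members were higher in sperm and 8 in egg.

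Small RNA biogenesis genes were split as well. Of 13 measured, 6 were higher in sperm, 6 were higher in egg and 1 did not pass (adjusted p of the list = 0.79), against 5 and 7 without composition scaling. DCL1 (LOC_Os03g02970), the Dicer of microRNAs, averaged 231 ± 37.7 in sperm and 52.5 ± 5.31 in egg (log2 fold change 2.13, SE 0.27, adjusted p = 8.4e-06), and DCL2a (LOC_Os03g38740) averaged 89.9 ± 13.2 and 9.06 ± 1.35 (3.31, SE 0.27, adjusted p = 1.5e-07). Of the genes higher in egg, NRPE1 (LOC_Os02g05880), the largest subunit of RNA polymerase V, averaged 124 ± 42.9 in egg and 3.12 ± 1.44 in sperm (log2 fold change -5.25, SE 0.48, adjusted p = 4.8e-07). RDR2 (LOC_Os04g39160), an RNA-dependent RNA polymerase of the RNA-directed DNA methylation pathway, averaged 28.4 ± 2.71 and 0.551 ± 0.485 (-5.49, SE 0.57, adjusted p = 1.5e-06).

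Of 9 measured DNA methylation genes, 6 were higher in sperm, 2 were higher in egg and 1 did not pass (adjusted p of the list = 0.18), against 5 and 2 with RLE and 3 and 2 without composition scaling. MET1b (LOC_Os07g08500), a maintenance methyltransferase, averaged 179.5 ± 36.3 in sperm and 4.06 ± 0.716 in egg (log2 fold change 5.45, SE 0.35, adjusted p = 2.6e-08). CMT2 (LOC_Os05g13790), a chromomethylase, averaged 109.6 ± 14.4 and 13.1 ± 1.67 (3.06, SE 0.25, adjusted p = 1.8e-07). CMT3b (LOC_Os03g12570) averaged 237 ± 259 in sperm and 4.82 ± 1.86 in egg (log2 fold change 5.62, SE 0.81, adjusted p = 2.6e-05), with 87.4, 86.2 and 536 in sperm replicates 1, 2 and 3. CMT3b was higher still in the vegetative cell, so vegetative RNA in the sperm preparations was not separated from expression in sperm. DDM1b (LOC_Os03g51230), a chromatin remodeler needed for DNA methylation, averaged 72.9 ± 39.5 in egg and 1.89 ± 2.67 in sperm (log2 fold change -5.44, SE 0.74, adjusted p = 1.7e-05). Among 4 measured demethylation genes 1 was higher in sperm and 2 were higher in egg, against 0 and 3 without composition scaling, and no list test was run on so few. ROS1a (LOC_Os01g11900), a DNA glycosylase, averaged 276 ± 73.4 in sperm and 86.3 ± 23.7 in egg (log2 fold change 1.68, SE 0.32, adjusted p = 0.00028), a call that ended without composition scaling, at 0.56. ROS1c (LOC_Os05g37350) averaged 32.4 ± 7.33 in egg and 0.359 ± 0.513 in sperm (log2 fold change -6.67, SE 0.79, adjusted p = 4.9e-06).

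The DNA replication licensing list held genes that load and fire replication origins, and also PCNA, which does neither. Of its 9 genes 7 were higher in sperm and 1 was higher in egg (adjusted p of the list = 0.040, and adjusted p = 0.47 with an estimated correlation). The counts were 6 and 2 with RLE, upper-quartile or no composition scaling. Without composition scaling the list did not pass (adjusted p = 0.053). MCM4 (LOC_Os01g36390) averaged 175 ± 11.6 in sperm and 16.6 ± 1.71 in egg (log2 fold change 3.40, SE 0.25, adjusted p = 7.8e-08), and ORC1 (LOC_Os06g08790) averaged 66.1 ± 11.9 and 4.66 ± 1.67 (3.81, SE 0.32, adjusted p = 2.3e-07). PCNA (LOC_Os02g56130), the sliding clamp of replication, was the 1 higher in egg, at 30.5 ± 4.599 against 0.971 ± 0.0664 (log2 fold change -4.94, SE 0.36, adjusted p = 7.0e-08). Of 5 measured members of Polycomb repressive complex 2, 2 were higher in sperm and 2 were higher in egg (adjusted p of the list = 0.79), against 1 and 2 with RLE or upper-quartile scaling and 1 and 3 without composition scaling. CLF (LOC_Os06g16390) averaged 66.1 ± 3.68 in sperm and 16.6 ± 3.15 in egg (log2 fold change 1.99, SE 0.26, adjusted p = 1.0e-05), while EZ1 (LOC_Os03g19480), which encodes another histone methyltransferase subunit, had 2 counts in sperm and an egg to sperm ratio of 115 (95% interval 31.6 to 951). FIE2 (LOC_Os08g04270) was called higher in sperm at 0.69 (adjusted p = 0.04) but stood at -0.47 without composition scaling and was also below 0 with limma on TPM. Its call was also lost with RLE or upper-quartile scaling, with no filter, with DESeq2 or the exact test, with only the 2 groups compared, with a replicate block, and without egg replicate 1 (0.56), egg replicate 2 (0.47), sperm replicate 2 (0.50) or sperm replicate 3 (0.62).

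Of 9 histone H3 genes 4 were higher in sperm and 3 in egg (adjusted p of the list = 0.75), against 2 and 4 with RLE, 3 and 3 with upper-quartile scaling and 1 and 5 without composition scaling. The H3.3 gene LOC_Os03g27310, a replacement histone, averaged 1325 ± 132 in sperm and 122 ± 13.7 in egg (log2 fold change 3.44, SE 0.40, adjusted p = 3.9e-06). Of 11 histone deacetylases 4 were higher in sperm and 6 in egg (adjusted p of the list = 0.79), against 2 and 7 without composition scaling. Of 7 cell cycle kinases and cyclins 0 were higher in sperm and 4 in egg (adjusted p of the list = 0.23), against 0 and 5 with RLE and 0 and 6 without composition scaling. All 4 measured YUCCA genes, which encode auxin biosynthesis enzymes, were called higher in sperm. Of them YUC4 was higher still in the vegetative cell, so for it vegetative RNA in the sperm preparations was not separated from expression in sperm. YUC8 (LOC_Os03g06654) averaged 87.5 ± 20.2 in sperm and 4.08 ± 2.904 in egg (log2 fold change 4.44, SE 0.43, adjusted p = 8.0e-07). BBM1 (LOC_Os11g19060), a BABY BOOM transcription factor known to promote embryo formation, averaged 4.65 ± 1.92 in sperm and had no count in egg. With TMM scaling it was at least 45.6-fold higher in sperm (adjusted p = 1.4e-05), a bound that would be lower without composition scaling.

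In all, 16009 of 19942 tested loci differed between sperm and egg, 7299 of them higher in sperm and 8710 higher in egg. Differences of more than 10-fold were fitted for 3339 loci higher in sperm and 5073 higher in egg, where fitted values of loci with few counts depend on the prior count. The most abundant loci by the fixed rule were LOC_Os01g57960 and LOC_Os05g41550 among those higher in sperm, and LOC_Os11g47760 and LOC_Os02g26700 among those higher in egg. LOC_Os05g41550 averaged 22625 ± 4272 in sperm and 1308 ± 529 in egg (log2 fold change 4.11, SE 0.92, adjusted p = 0.00093), and LOC_Os11g47760 averaged 2895 ± 753 in egg and 14.4 ± 2.699 in sperm (log2 fold change -7.65, SE 0.59, adjusted p = 1.0e-07). LOC_Os01g57960 was at the threshold (adjusted p = 0.0498) and lost its call with RLE, upper-quartile or no composition scaling, with limma on TPM, and without egg replicate 1 (1.7961), egg replicate 2 (1.88) or sperm replicate 1 (2.26). The sperm marker list passed the list test (adjusted p = 0.00051, and adjusted p = 0.27 with an estimated correlation), as did the ovule and carpel list (0.0030, and adjusted p = 0.27 with an estimated correlation), the photosynthesis list (2.8e-05, and adjusted p = 0.27 with an estimated correlation) and the pollen vegetative list, 8 of 10 higher in sperm or, without composition scaling, 7 higher and 1 lower (0.012, and adjusted p = 0.49 with an estimated correlation). With each of the 6 compared libraries left out in turn, some counts of list members moved. Members higher in sperm numbered 5 to 6 for DNA methylation and 1 to 2 for Polycomb repressive complex 2. They numbered 2 to 4 for histone H3 and 6 to 7 for DNA replication licensing. Members higher in egg numbered 7 to 8 for ovule and carpel markers, 2 to 3 for Polycomb repressive complex 2 and 5 to 6 for histone deacetylases. They numbered 2 to 4 for histone H3, 1 to 2 for DNA replication licensing and 4 to 5 for cell cycle kinases and cyclins. The other counts stayed as they were. The share of changed loci that were higher in sperm was 45.6%, and it was 31.4% without composition scaling and 31.0% with limma on TPM.

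Vegetative cell against egg compared the companion cell of the sperm with the female gamete. Some genes higher in the vegetative cell than in egg were higher still in sperm, MET1b among them. For these, sperm RNA in the vegetative preparations was not separated from expression in the vegetative cell. DNA methylation genes included 4 of 9 higher in the vegetative cell and 2 higher in egg (adjusted p of the list = 0.53), but 3 and 6 without composition scaling. CMT3b averaged 3014 ± 381 in the vegetative cell and 4.82 ± 1.86 in egg (log2 fold change 9.29, SE 0.95, adjusted p = 1.3e-06), and DRM3 (LOC_Os05g04330), of the domains-rearranged methyltransferase family, averaged 990.3 ± 113 and 33.8 ± 3.09 (4.87, SE 0.51, adjusted p = 1.6e-06). MET1b averaged 86.8 ± 22.8 in the vegetative cell (log2 fold change 4.41, SE 0.33, adjusted p = 1.2e-07). DDM1b was higher in egg (log2 fold change -6.26, SE 0.84, adjusted p = 1.4e-05). Of the 4 demethylation genes 3 were higher in egg, and 4 were when adjusted over the list alone, with RLE or upper-quartile scaling, or without composition scaling. ROS1c averaged 1.405 ± 1.498 in the vegetative cell (log2 fold change -4.47, SE 0.68, adjusted p = 4.8e-05), and ROS1a, at 52.3 ± 6.89 in the vegetative cell, did not pass over all loci (log2 fold change -0.72, SE 0.32, adjusted p = 0.051) but passed under 11 of the alternatives tried.

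Of the 16 ARGONAUTE genes 4 were higher in the vegetative cell and 8 were higher in egg (adjusted p of the list = 0.35), but 2 and 8 with RLE or upper-quartile scaling and 0 and 15 without composition scaling. AGO4a (LOC_Os01g16870) averaged 309 ± 21.7 in egg and 24.2 ± 1.85 in the vegetative cell (log2 fold change -3.68, SE 0.33, adjusted p = 4.1e-07), and AGO1c (LOC_Os02g58490) averaged 40.4 ± 9.46 and 1.15 ± 0.204 (-5.12, SE 0.38, adjusted p = 1.1e-07). Small RNA biogenesis genes included 3 of 13 higher in the vegetative cell and 7 higher in egg (adjusted p of the list = 0.57), and 0 and 12 without composition scaling. DCL4 (LOC_Os04g43050), a Dicer of small interfering RNAs, averaged 28.1 ± 4.82 in egg and 1.25 ± 0.291 in the vegetative cell (log2 fold change -4.47, SE 0.39, adjusted p = 3.4e-07), and NRPD2 (LOC_Os04g54840), a subunit shared by RNA polymerases IV and V, averaged 60.2 ± 2.99 and 6.03 ± 3.105 (-3.33, SE 0.35, adjusted p = 1.8e-06).

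Of 5 Polycomb repressive complex 2 members 3 were higher in the vegetative cell and 1 in egg (adjusted p of the list = 0.22), but 1 and 3 without composition scaling. The 1 higher in egg was EZ1 (log2 fold change -0.99), whose call was lost without egg replicate 1 (-1.11), egg replicate 3 (-0.87) or vegetative replicate 1, 2 or 3 (-0.98, -1.0002 and -0.91). EMF2b (LOC_Os09g13630) averaged 210.5 ± 5.62 in the vegetative cell and 18.2 ± 5.38 in egg (log2 fold change 3.53, SE 0.41, adjusted p = 4.1e-06), a call that limma on TPM did not make. Replication licensing genes included 6 of 9 higher in the vegetative cell and 3 higher in egg (adjusted p of the list = 0.51), but 3 and 3 with RLE or upper-quartile scaling and 0 and 6 without composition scaling. MCM3 (LOC_Os05g39850) averaged 53.5 ± 10.4 in the vegetative cell and 10.7 ± 1.801 in egg (log2 fold change 2.32, SE 0.27, adjusted p = 3.5e-06), and it stood at -0.37 without composition scaling. The 6 replication licensing genes called higher in the vegetative cell were all higher still in sperm. For them, sperm RNA in the vegetative preparations was not separated from expression in the vegetative cell. MCM2 (LOC_Os11g29380) was higher in egg (log2 fold change -1.88, SE 0.30, adjusted p = 7.7e-05). No cell cycle kinase or cyclin of 7 was higher in the vegetative cell and 5 were higher in egg (adjusted p of the list = 0.17), against 0 and 7 without composition scaling. Of 11 histone deacetylases 2 were higher in the vegetative cell and 4 in egg (adjusted p of the list = 0.79), but 2 and 7 with RLE, 2 and 6 with upper-quartile scaling and 2 and 9 without composition scaling. SRT702 (LOC_Os12g07950), a sirtuin, averaged 131 ± 17.6 in the vegetative cell and 4.22 ± 1.46 in egg (log2 fold change 4.94, SE 0.35, adjusted p = 7.8e-08). Histone H3 genes included 2 of 9 higher in the vegetative cell and 1 in egg (adjusted p of the list = 0.79), but 2 and 2 with RLE or upper-quartile scaling and 0 and 7 without composition scaling. Of 4 auxin biosynthesis genes 2 were higher in the vegetative cell and 0 in egg, against 1 and 2 without composition scaling. YUC4 (LOC_Os01g12490) averaged 139.9 ± 34.7 in the vegetative cell and had 3 counts in egg. With TMM scaling the ratio was 1476 (95% interval 504 to 7164), and it would be lower without composition scaling.

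Of the pollen vegetative cell markers 9 of 10 were higher in the vegetative cell than in egg (adjusted p of the list = 0.00019, and adjusted p = 0.47 with an estimated correlation), against 8 higher and 1 lower without composition scaling. MADS63 (LOC_Os06g11970), a MADS-box factor of late pollen, averaged 66.3 ± 9.84 in the vegetative cell and 0.613 ± 0.163 in egg (log2 fold change 6.73, SE 0.48, adjusted p = 8.9e-08). MADS62 (LOC_Os08g38590) had no count in egg. With TMM scaling it was at least 802-fold higher in the vegetative cell (adjusted p = 1.7e-06), a bound that would be lower without composition scaling. The 5 sperm markers were also higher in the vegetative libraries than in egg (adjusted p of the list = 0.0016, and adjusted p = 0.27 with an estimated correlation), and 4 of them were without composition scaling, where DUO1 (LOC_Os04g46384) lost its call. The ovule and carpel list (adjusted p = 0.0033) and the photosynthesis list (adjusted p = 2.8e-05) were lower in the vegetative cell than in egg, each with adjusted p = 0.27 with an estimated correlation.

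In all, 15556 of 19942 loci differed between the vegetative cell and egg, 6799 higher in the vegetative cell and 8757 higher in egg, and 3334 and 5162 of them by more than 10-fold. The most abundant loci by the fixed rule were LOC_Os11g43640 and LOC_Os10g40090 among those higher in the vegetative cell, and LOC_Os11g47760 and LOC_Os09g30412 among those higher in egg. LOC_Os11g43640 averaged 63589.8 ± 16246 in the vegetative cell and 19.8 ± 21.7 in egg (log2 fold change 11.65, SE 1.76, adjusted p = 4.4e-05). With each of the 6 compared libraries left out in turn, some counts of list members moved. Members higher in the vegetative cell numbered 9 to 10 for pollen vegetative cell markers and 2 to 4 for ARGONAUTE family. They numbered 3 to 6 for DNA replication licensing and 2 to 3 for auxin biosynthesis. Members higher in egg numbered 3 to 4 for DNA demethylation, 0 to 1 for Polycomb repressive complex 2 and 6 to 7 for small RNA biogenesis. They numbered 1 to 2 for histone H3 and 2 to 3 for reference. The other counts stayed as they were. The share of changed loci higher in the vegetative cell was 43.7%, but it was 16.3% without composition scaling and 15.98% with limma on TPM. Without composition scaling 1434 of the called loci were called with the opposite sign.

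Sperm against vegetative cell compared the gamete with its companion cell from the same pollen isolations. Of 16 measured ARGONAUTE genes, 13 were called higher in sperm, 0 were lower and 3 did not pass, against 15 higher and 0 lower without composition scaling (adjusted p of the list = 0.0018, and adjusted p = 0.47 with an estimated correlation). AGO13 averaged 75.5 ± 10.2 in sperm and 10.4 ± 2.71 in the vegetative cell (log2 fold change 2.86, SE 0.29, adjusted p = 4.1e-06), AGO4a averaged 163 ± 48.7 and 24.2 ± 1.85 (2.75, SE 0.32, adjusted p = 8.9e-06), and AGO11 (LOC_Os03g47820) averaged 105 ± 29.5 and 16.1 ± 3.37 (2.71, SE 0.36, adjusted p = 2.3e-05). Small RNA biogenesis genes included 8 of 13 higher in sperm and 1 lower (adjusted p of the list = 0.14), against 9 and 0 without composition scaling. NRPD1a (LOC_Os04g48370), a largest subunit of RNA polymerase IV, averaged 59.6 ± 4.76 in sperm and 5.77 ± 2.28 in the vegetative cell (log2 fold change 3.37, SE 0.37, adjusted p = 6.2e-06), and DCL1 averaged 50.7 ± 6.89 in the vegetative cell (log2 fold change 2.19, SE 0.27, adjusted p = 1.6e-05).

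**Figure D3:**
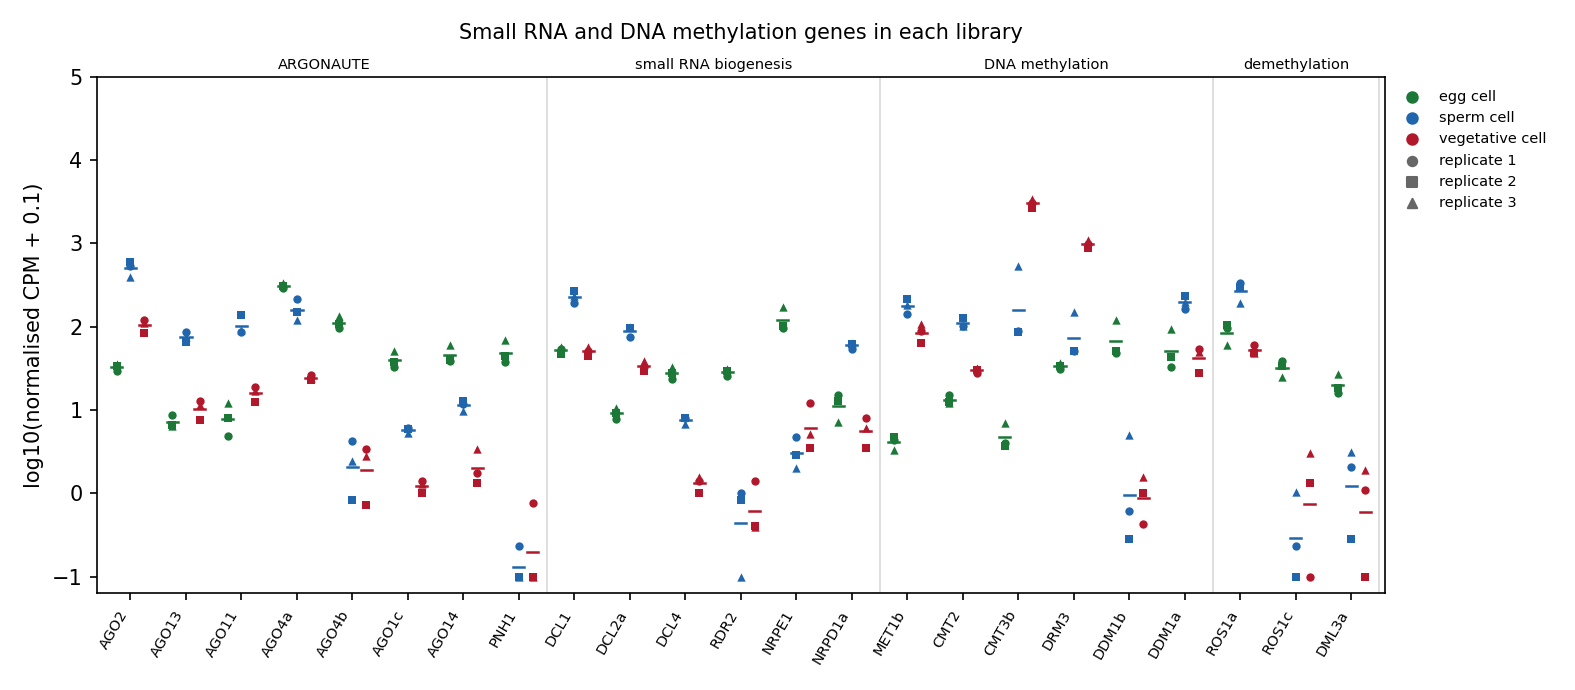
Small RNA, DNA methylation and demethylation genes (x axis) in each library as log10 of normalised CPM plus 0.1 (y axis), with colours for cell types, shapes for replicates and bars for the mean of the plotted values. AGO2 and AGO13 were highest in sperm, AGO4b, AGO1c, AGO14 and PNH1 were highest in egg, and CMT3b and DRM3 were highest in the vegetative cell (3014 and 990.3 on average).

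DNA methylation genes went both ways, with 5 of 9 higher in sperm and 2 higher in the vegetative cell (adjusted p of the list = 0.53), against 7 and 2 without composition scaling. DDM1a (LOC_Os09g27060) averaged 198 ± 33.9 in sperm and 43.3 ± 13.7 in the vegetative cell (log2 fold change 2.20, SE 0.40, adjusted p = 0.00032), and CMT2 averaged 30.1 ± 2.39 in the vegetative cell (log2 fold change 1.86, SE 0.24, adjusted p = 2.2e-05). DRM3 was higher in the vegetative cell (log2 fold change -3.56, SE 0.48, adjusted p = 2.9e-05), with 50.4, 50.5 and 151 in sperm replicates 1, 2 and 3. Of the 4 demethylation genes 2 were higher in sperm, and 3 were without composition scaling. The 2 were ROS1a (log2 fold change 2.40, SE 0.33, adjusted p = 3.5e-05) and ROS1d (LOC_Os05g37410), at 40.9 ± 16.1 in sperm and 12.7 ± 2.21 in the vegetative cell (1.69, SE 0.34, adjusted p = 0.00074). Of 5 Polycomb repressive complex 2 members 3 were higher in the vegetative cell and 0 in sperm (adjusted p of the list = 0.095), but 2 were higher in sperm and 3 in the vegetative cell without composition scaling. EMF2a (LOC_Os04g08034) averaged 28.6 ± 3.84 in the vegetative cell and 1.16 ± 0.651 in sperm (log2 fold change -4.70, SE 0.46, adjusted p = 3.1e-06), and EMF2b averaged 13.9 ± 8.47 in sperm (log2 fold change -3.94, SE 0.42, adjusted p = 5.6e-06).

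Replication licensing genes included 8 of 9 higher in sperm and 1, PCNA, higher in the vegetative cell (adjusted p of the list = 0.021, and adjusted p = 0.47 with an estimated correlation). With the replicate number as a block, which pairs the isolations, the list's adjusted p was 0.072. MCM4 averaged 25.8 ± 1.39 in the vegetative cell (log2 fold change 2.76, SE 0.25, adjusted p = 2.1e-06), and MCM5 (LOC_Os02g55410) averaged 162 ± 8.28 in sperm and 29.5 ± 7.42 in the vegetative cell (2.46, SE 0.30, adjusted p = 1.2e-05). Cell cycle genes included 2 of 7 higher in sperm and 1 lower (adjusted p of the list = 0.79), against 4 and 0 without composition scaling. Histone deacetylases included 5 of 11 higher in sperm and 5 lower (adjusted p of the list = 0.79), against 5 and 3 without composition scaling. SRT701 (LOC_Os04g20270) averaged 180.1 ± 62.00 in sperm and 27.8 ± 3.28 in the vegetative cell (log2 fold change 2.70, SE 0.32, adjusted p = 1.0e-05), while SRT702 averaged 11.8 ± 3.44 in sperm (log2 fold change -3.48, SE 0.32, adjusted p = 2.4e-06). Histone H3 genes included 3 of 9 higher in sperm and 2 lower (adjusted p of the list = 0.79), against 3 and 0 with upper-quartile scaling and 4 and 0 without composition scaling. Of the 2 lower, LOC_Os11g05730 (log2 fold change -1.51) lost its call without sperm replicate 1, 2 or 3 (-1.62, -1.55 and -1.41) or vegetative replicate 1 or 3 (-1.29 and -1.45). Its call was also lost with the replicate block, which pairs the isolations (-1.485), with upper-quartile scaling (-1.33) and with no filter (-1.493). CENH3 (LOC_Os05g41080), the centromeric variant, averaged 19.02 ± 2.04 in sperm and 4.93 ± 1.51 in the vegetative cell (log2 fold change 1.95, SE 0.38, adjusted p = 0.00049).

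Of 4 auxin biosynthesis genes 3 were higher in sperm and 1 was higher in the vegetative cell. YUC8 averaged 7.48 ± 0.463 in the vegetative cell (log2 fold change 3.55, SE 0.43, adjusted p = 1.2e-05). YUC4 was higher in the vegetative cell (log2 fold change -4.45, SE 0.57, adjusted p = 1.9e-05), with 4.32, 1.84 and 13.7 in sperm replicates 1, 2 and 3. BBM1 averaged 1.46 ± 0.741 in the vegetative cell (log2 fold change 1.64, SE 0.62, adjusted p = 0.036), and its call was lost when any 1 of the 6 libraries was left out, where log2 fold changes ran from 1.24 to 1.88. Of 5 tapetum and anther wall markers that were measured among 14 listed, 2 were higher in sperm and 0 in the vegetative cell (adjusted p of the list = 0.73), against 3 and 0 without composition scaling. Against egg they included 2 higher in sperm and 2 in egg (adjusted p of the list = 0.79, and 1 and 3 with RLE or without composition scaling), and 1 higher in the vegetative cell and 3 in egg (adjusted p of the list = 0.57, and 0 and 4 without composition scaling). Of the ovule and carpel markers 1 was higher in sperm and 3 in the vegetative cell (adjusted p of the list = 0.53), against 1 and 0 without composition scaling. The 1 higher in sperm was MADS1, with 3 counts in the vegetative cell and 38 in sperm. Its call was lost without sperm replicate 3, vegetative replicate 1 or vegetative replicate 2. Of 17 photosynthesis genes 1 was higher in the vegetative cell (adjusted p of the list = 0.81), but 3 were higher in sperm without composition scaling.

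In all, 12512 of 19942 loci differed between sperm and vegetative cell, 6498 higher in sperm and 6014 higher in the vegetative cell, and 1716 and 2919 of them by more than 10-fold. The most abundant loci by the fixed rule were LOC_Os05g07070 and LOC_Os03g42464 among those higher in sperm, and LOC_Os11g43640 and LOC_Os10g40090 among those higher in the vegetative cell. LOC_Os05g07070 averaged 4427 ± 369.7 in sperm and 772 ± 139.5 in the vegetative cell (log2 fold change 2.52, SE 0.51, adjusted p = 0.00067). LOC_Os11g43640 measured 1949, 2122 and 8984 in sperm replicates 1, 2 and 3, and its call (log2 fold change -3.87, SE 1.27, adjusted p = 0.016) was lost without sperm replicate 1, at -3.53, or without sperm replicate 2, at -3.53. The sperm markers (adjusted p = 0.0033, and adjusted p = 0.31 with an estimated correlation) and the pollen vegetative markers (adjusted p = 0.0011, and adjusted p = 0.47 with an estimated correlation) passed the list test in opposite directions. With each of the 6 compared libraries left out in turn, some counts of list members moved. Members higher in sperm numbered 0 to 1 for ovule and carpel markers, 4 to 5 for DNA methylation, 12 to 13 for ARGONAUTE family, 7 to 8 for small RNA biogenesis and 4 to 5 for histone deacetylases. They numbered 7 to 8 for DNA replication licensing, 2 to 3 for cell cycle kinases and cyclins, 2 to 3 for auxin biosynthesis and 0 for BABY BOOM family. Members higher in the vegetative cell numbered 2 to 3 for ovule and carpel markers, 0 to 3 for photosynthesis and 0 to 1 for DNA demethylation. They numbered 1 to 2 for small RNA biogenesis and 0 to 2 for histone H3. The other counts stayed as they were. The share of changed loci higher in sperm was 51.9%, and it was 73.9% without composition scaling and 72.6% with limma on TPM.

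Genes higher in 1 cell type than in both others numbered 6666 for the egg, 4090 for sperm and 3771 for the vegetative cell. The egg set held all 8 ovule and carpel markers and all 17 measured photosynthesis genes, 25 of its 57 list members. It also held 8 ARGONAUTE genes, among them AGO4a, AGO4b, AGO14 and PNH1, and 5 small RNA biogenesis genes, DCL4, RDR2, RDR6, NRPD2 and NRPE1. For none of the egg set was expression in the egg cell separated from ovary tissue left on the dissected cells. The sperm set held the 5 sperm markers, 7 ARGONAUTE genes, among them AGO2, AGO11, AGO13 and MEL1, 5 small RNA biogenesis genes with DCL1 and NRPD1a, and 7 replication licensing genes, MCM2, MCM3, MCM4, MCM5, MCM7, ORC1 and CDC6. It also held 4 DNA methylation genes, MET1b, CMT2, DRM2 and DDM1a. The vegetative set held 9 pollen vegetative markers, the DNA methylation genes CMT3b and DRM3, and EMF2a and EMF2b of Polycomb repressive complex 2. In 20 simulations with no effect each set held 0 loci. That was near certain beforehand, since data without effects give almost no calls, so it does not bear on the overlap. Independent lists of the same sizes would share 3825, 2378 and 2050 loci. Part of the excess can come from the libraries that the comparisons share. Without composition scaling the sets numbered 10026, 3589 and 1700. All 57 list members in the egg set, the UBQ5 and GAPC loci of doubtful name included, were in it then too, as were 28 of 39 in the sperm set and 15 of 17 in the vegetative set. Of the genes named here, MEL1, DRM2, DDM1a, MCM2 and EMF2a left their set. With a minimum of 4-fold from both other cell types, 5291, 2213 and 2551 genes passed.

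The reference list of 5 measured genes includes UBQ5 and GAPC, 2 names that are in doubt because a RefSeq gene table puts them on another chromosome than their identifiers do, and the counts and list tests include both loci. In sperm 0 were higher and 4 lower than in egg, both doubtful loci among the 4 (adjusted p of the list = 0.16). In the vegetative cell 1 was higher and 3 lower than in egg, both among the 3 (adjusted p of the list = 0.79), against 1 and 4 without composition scaling. Between sperm and vegetative cell 3 were lower in sperm, 1 of them the GAPC locus (adjusted p of the list = 0.14), and without composition scaling 2 were higher and 2 lower. ACT1 (LOC_Os03g50885), an actin gene, averaged 3556 ± 474 in the vegetative cell, 195 ± 131 in sperm and 108 ± 6.14 in egg (log2 fold change 5.04, SE 0.61, adjusted p = 6.1e-06 for vegetative cell against egg). It measured 127, 112 and 347 in sperm replicates 1, 2 and 3. Non-overlapping libraries were found for 81.7% of loci between sperm and egg, 81.0% between vegetative cell and egg and 66.4% between sperm and vegetative cell, where chance gives 10%.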

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

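Leaving out the 3 most abundant loci, and the list tests, cell-type sets and shared pollen set without composition scaling, were chosen after the data were seen, and the other alternatives before. Without composition scaling the median log2 fold change of all loci shifted by -1.16 (sperm against egg), -2.65 (vegetative cell against egg) and 1.49 (sperm against vegetative cell), and with limma on log2(TPM + 1) by -0.98, -1.78 and 0.54. RLE shifted it by -0.42, -0.32 and -0.09, and upper-quartile scaling by -0.14, -0.31 and 0.17. Genes higher in the vegetative cell than in egg then numbered 2775 without composition scaling, 2686 and 2828 with limma on TPM (pseudocounts 1 and 0.1), and genes lower numbered 14215, 14125 and 13996. Between sperm and vegetative cell 10023 were higher without composition scaling, and 3541, 3417 and 3596 were lower under those settings. Genes higher in sperm than in egg numbered 4793 with limma at pseudocount 0.1. List calls numbered 0 with an estimated correlation and 32 with fry, which tests lists alone and not against other genes, and 12 without composition scaling. Without composition scaling the egg set numbered 10026, the vegetative set 1700 and the set higher in both pollen preparations than egg 2001. Sperm-enriched genes numbered 2213 at a minimum of 4-fold, and loci detected at 5 CPM numbered 8296 in sperm and 5949 in the vegetative cell. Every other count of changed, enriched or detected genes stayed within 1.5 times its value. Apart from the thresholds themselves (4-fold and 5 CPM) and the TMM factors that the setting without composition scaling leaves out, the cause was not tested. Leaving out 1 library at a time gave 15952 to 17198 changed genes for sperm against egg (7014 to 7706 higher, 8617 to 9492 lower). It gave 15137 to 16170 for vegetative cell against egg (6604 to 6959 higher, 8478 to 9211 lower), and 11623 to 13330 for sperm against vegetative cell (5884 to 7079 higher, 5739 to 6251 lower). List calls stayed at 13. Enriched genes ran from 6432 to 7152 (egg), 3692 to 4496 (sperm) and 3574 to 4029 (vegetative cell), and detected loci from 18291 to 18999, 13447 to 15145 and 10808 to 10945. Without sperm replicate 3, which stood apart, sperm against egg gave 17198 changed genes, sperm against vegetative cell 13330, and enriched genes were 7152, 4496 and 4029. With the replicate block the 3 comparisons gave 14478 (6126 higher, 8352 lower), 15094 (5890 and 9204) and 10842 (5793 and 5049). In sperm against vegetative cell 10537 of 12512 called loci were kept with their direction. Of the 4 list calls there 3 were kept and the replication licensing list was not (adjusted p 0.072). Of 76 gene results there 58 could be recomputed, 57 kept their side of the threshold and the histone H3 gene LOC_Os11g05730 lost its call. Against the egg, which shares only numbers, it ended the call of FIE2 and added ROS1a and the H3.3 gene LOC_Os06g04030. Median, mean and test of a list differed in sign for ARGONAUTE and small RNA biogenesis (sperm against egg), DNA methylation, histone deacetylases and histone H3 (vegetative cell against egg), and photosynthesis, histone deacetylases and histone H3 (sperm against vegetative cell). A 2-fold change was recovered in 0% of simulated genes, with 200 of 19942 changed, which sets a stricter adjusted threshold than the real fits had, so the limit set by depth was not measured.

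The fixed rule allowed 228 gene results, with 4034 recomputed values. Of these 3847 kept direction and side of the threshold, 98 lost the call, 40 gained one and 49 changed direction. All changes of direction came without composition scaling or with limma on TPM. The first setting differs from the main fit only in leaving out the TMM factors, so its changes come from them. Limma on TPM leaves them out too but also differs in model, and these parts were not separated. The log2 fold changes then, in the order no composition scaling, limma with pseudocount 1 and limma with pseudocount 0.1, were as follows. In sperm against egg they were DPW (-0.12, -0.1, -0.10), FIE2 (-0.47, -0.51, -0.52) and H3.3 LOC_Os06g04030 (-0.14, -0.20, -0.20). In vegetative cell against egg they were CLF (-0.48, -0.50, -0.53), EMF2a (-1.18, -1.08, -1.18), H3.3 LOC_Os03g27310 (-0.86, -0.89, -0.90), MCM3 (-0.37, -0.37, -0.39), CDC6 (-0.31, -0.32, -0.36), ORC1 (-0.61, -0.48, -0.55), YUC8 (-1.73, -1.12, -1.54), YUC3 (-1.98, -1.22, -1.95) and UBC (-2.24, -2.17, -2.25), and the H3.3 LOC_Os04g34240 gene was at -0.055 without composition scaling. In sperm against vegetative cell they were CLF (1.34, 1.30, 1.35), HDA702 (0.29, 0.27, 0.28), H3 LOC_Os11g05730 (0.041, 0.064, 0.075) and EF1A (1.23, 1.12, 1.24).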

Other observations

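The set higher in both pollen preparations, the tests of explanations, the joined lists and the splits in this part were chosen after the result was seen. The test of vegetative material and that of the lists between egg libraries were each revised once after a first result.

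Transcripts higher in both pollen preparations than in egg numbered 4833, and 1172 of these did not differ between sperm and vegetative cell at the threshold. Independent lists would share 2489, though part of the overlap can come from the shared egg libraries. The 20 simulations with no effect gave 0, which was near certain with almost no calls and does not measure that part. The set depended on scaling: without composition scaling it numbered 2001, and 16 of its 39 list members stayed in it. Of these 16, 4 were sperm markers (HAP2/GCS1, GEX1, GEX2 and GEX3), 7 were pollen vegetative markers (RUPO, MADS62, MADS68, profilin and the beta-expansins), and the others were MET1b, CMT3b, HDA701, YUC4 and BBM1. Since markers of both pollen cell types are in the set, expression in both was not separated from material of 1 cell type in the other's preparation. As scaled in the report, the set also held AGO2, AGO11 and AGO17, the Dicer genes DCL2a and DCL2b, the DNA methylation genes CMT2 and DRM3, and 6 replication licensing genes, all of which left it without composition scaling. AGO1a, RDR1, CLF and the anther gene WDA1 were among the 1172, and they left the set too. CLF averaged 66.1 ± 3.68 normalised CPM in sperm, 75.5 ± 14.2 in the vegetative cell and 16.6 ± 3.15 in egg, and its change against egg in the vegetative cell was -0.48 without composition scaling. Loci that differed in all 3 comparisons numbered 6982, and 905 differed in none.

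Sperm replicate 3 had higher vegetative cell transcripts than sperm replicates 1 and 2. Over 1494 vegetative-enriched loci of at least 50 CPM, the log2 ratio of sperm replicate 3 to the other two had a median of 1.29 (quartiles 0.025 and 1.96), which argues against a few abundant loci, since these would lower all others. Its total count was 96.1% of their mean and lay between them, which argues against depth. Vegetative material carried into the preparation may explain it and stays open. Sperm-enriched loci were lower in sperm replicate 3 (median log2 ratio -0.77), for a reason that was not tested. With sperm replicates 1 and 2 scaled down by that ratio, the excess was 18.3% of the vegetative level (quartiles 12.5 and 25.6, above 0 at 97.3% of loci). Under that allowance a locus with no rise in sperm replicate 3 also counts as excess. The quartile ratio was 2.04, where 1 source was set to give under 2. A first version without that allowance gave 12.1% (0.678 and 19.6). A biological difference between isolations was not tested.

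Photosynthesis and ovule genes in the egg libraries (the most abundant were LOC_Os09g17740 at 83.9 and MADS13 at 149 normalised CPM) could come from ovary tissue left on the dissected cells. Between egg libraries the lists differed in median log2 ratio by up to 0.866 (largest of 3 pairs of libraries), a difference between single libraries that decides nothing. One tissue, several tissues, or expression in the egg cell itself stay open. Cultivar, growth site and kit cannot be told apart from cell type, because 0 egg libraries share them with a sperm or vegetative library.

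The loci LOC_Os09g08910 and LOC_Os01g08350, singled out after their values were seen, took 0.613 to 14.1% and 0.268 to 7.10% of the counts, with the highest shares in sperm replicate 3. The ratio of their counts lay between 1.81 and 2.32 in all 9 libraries (coefficient of variation 7.93%), which is consistent with 1 RNA source feeding both, though what that source is cannot be read from these files and no biological explanation was tested. Their weight on the number of changed genes was looked at with TMM scaling only, and not without composition scaling. With TMM scaling and without them and LOC_Os01g57960, 15957 genes changed between sperm and egg, against 16009.

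A hypothesis, formed after the list counts were seen, was that small RNA and chromatin genes differ between sperm and egg more often than other genes. It joined the lists of DNA methylation, DNA demethylation, Polycomb repressive complex 2, ARGONAUTE, small RNA biogenesis and histone deacetylase genes, and left out histone H3. Of 58 measured members 53 were called (91.4%, against 80.3% of all tested loci), and without composition scaling 46 were (79.3%, against 79.8%). The values do not support it, since the lists were joined after their calls were seen and no excess was found without composition scaling.

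Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. In fits of the 6 libraries the real splits gave 14991, 15459 and 11341 changed genes for sperm against egg, vegetative cell against egg and sperm against vegetative cell, and the highest of the others gave 0 in each, so 1 of 10 splits gave as many. The other splits put both cell types on each side, which widens the spread within sides. Their 0 therefore does not measure what random differences between libraries would give.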
